A study of Mus musculus with 18 samples.

How the data were processed

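The series holds 18 arrays with 2 dyes, on which 9 pools of embryonic mouse neocortex, 3 each from its rostral, middle and caudal parts, were hybridised against each other. Per the labels, each array carried a pool in Cy3 and another in Cy5. Each pool was on 4 arrays, 2 in each dye, and 0 arrays held pools of the same number. Only pools of different regions shared an array. The labels give 4 embryos as the source of the tissue and do not say which embryos gave which pool.

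The values were analysed as deposited by the authors, who gave 1 log2 ratio per probe and array in a table of 21998 probes. The base of the logarithm was read from the values: the highest value on every array is log2 of 100000, a capped ratio, and the next highest value in the table is 7.57. Scanner, background correction, filters, normalization and the direction of the ratio are not given in the sources used here. Ratios were read as Cy5 over Cy3, by the order of the channels. By a rule set before the data were examined this direction was kept, as likely, because genes reported as rostral and as caudal in textbooks went the reported way in rostral against caudal (camera, unadjusted p = 0.00338, Up, and 0.00953, Down). With an estimated correlation these were 0.0964 and 0.0402, and neither list passed after adjustment (0.515 and 0.442). Arrays shared a common pattern with the dyes: each correlated with the mean of the other 17 at 0.223 to 0.478 across features. With that pattern removed, the correlation of an array with the values predicted for it from the other 17 arrays was between -0.06 and 0.22, median 0.03. These are correlations across features, which are not independent replicates.

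Of the probes, 232 were Gapdh control spots, which were left out of the tests, and 21766 were not. Of the latter, 16632 had 1 gene symbol in the platform annotation, 139 had several and 4995 are unnamed here. The gene ID was found in the reference table for 15952 of the probes with 1 symbol and not for 680, and 0 symbols changed. Capped ratios (1477, between 39 and 221 on an array) were set to missing, a choice made after seeing the data. Arrays held between 1032 and 3494 missing values. Array medians lay between -0.09 and 0.61, so by the rule set in advance, which centres where a median differs from 0 by over 0.1, each array was centred on its median. Without centring, the median difference over all features was -0.07 for rostral against caudal, 0.10 for rostral against middle and -0.17 for middle against caudal. All differences are relative to the array medians. A feature entered with values on at least 12 arrays and on at least 2 arrays of each pool, which left 18525 features, 12571 of them with values on all 18 arrays.

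Pool values were estimated per feature by least squares over its arrays, with 1 coefficient per pool, summing to 0, and 1 for the dye. The pool, not the array, was the sample: limma 3.58.1 (lmFit and eBayes, R 4.3.3) was fitted to the 9 pool values with region as the factor, which left 6 residual degrees of freedom and added 1.26 prior degrees of freedom. The median residual SD was 0.256 between arrays and 0.151 between pools. Contrasts were rostral against caudal, rostral against middle, middle against caudal, and middle against the mean of the ends, and the F test asked for any difference among the 3 regions. P-values were adjusted by Benjamini and Hochberg over all features tested, and features with an adjusted p under 0.05 are said to pass. All tests were two-sided.

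Gene lists were fixed before the data were examined, as were the main design, the alternatives not said to be added and the rule for the genes that the text names. The 21 lists were reported rostral genes, reported caudal genes, the FGF pathway, WNT and BMP genes of the dorsal midline, Cajal-Retzius cells, radial glia, intermediate progenitors, cortical neurons, proliferation, Eph receptors with ephrins and cadherins, retinoid genes, ventral telencephalon, choroid plexus, diencephalon, meninges, red blood cells, endothelium, microglia, surface epithelium, immediate early and heat shock genes, and Xist with Y-linked genes. The list of Eph receptors, ephrins and cadherins also held Lmo3, Lmo4, Crym and Id2, which belong to none of these families. With the ribosomal protein genes, 22 sets were tested by camera with a preset correlation of 0.01, adjusted over the sets within a comparison. Camera compares a set with all other features. The same test with a correlation estimated from the 9 pools and fry, which asks whether the genes of a set move one way on balance, were alternatives. With an estimated correlation 0 of the 22 sets passed in any of the 3 comparisons. The 1 feature of a gene with values on most arrays stood for it. Per list, genes were counted past an adjusted p of 0.05 over all features and adjusted over the list alone.

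For each pair of regions the text names, among features with 1 gene, up to 12 genes per direction: the largest differences among those that passed with no overlap between the pools, and, where fewer than 12 passed, those with the smallest p, said not to pass. It also names every measured member of the reported rostral and caudal lists for rostral against caudal, members of other lists that passed or had the smallest p, and the 10 features with the smallest p for the F test and for the middle against the ends.

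The fit was tested on simulated data for rostral against caudal, with 18525 features of which 50 each were changed by 0.25, 0.5, 1 and 2 on the log2 scale. It recovered 0% of those changed by 0.25, 26% at 0.5, 58% at 1 and 70% at 2, and called 1 of 18325 unchanged features. A count of 0 below therefore does not show that 2 regions are alike. Of the unchanged features 2.76% had an unadjusted p under 0.05, so the test was conservative in this simulation. The unadjusted counts given below are therefore not to be read against a share of 0.05. A fit that took the 18 arrays as independent called 149 of the unchanged features. The alternatives were no centring, arrays scaled to equal spread, features on all 18 or on at least 10 arrays, leaving out the noisiest 25% of features, arrays as the unit, no dye term, the replicate number as a block, a robust prior, a minimum difference of 0.5, and leaving out each pool and each array. Added after seeing the data were capped ratios kept, leaving out the 4 arrays with over 100 capped ratios, the Gapdh control spots as a covariate, a lowess correction of each array on the mean of the other 17 (span 0.4), and sets of pools that share arrays as a block. Figures were drawn with matplotlib 3.10.9 (Python 3.11.15).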

Results

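Neocortex of MF1 mouse embryos was compared at mid-gestation, when the cortical wall holds progenitors and the earliest neurons and regional identity is being laid down along the rostrocaudal axis. RNA of 9 pools, 3 rostral, 3 middle and 3 caudal, was hybridised in pairs on 18 arrays with 2 dyes. Each pool was measured on 4 arrays, 2 in each dye, and 6 arrays joined each pair of regions. The tissue came from 4 embryos, per the labels, which do not say that the pools of a region came from separate embryos. The p-values therefore measure the spread between these pools, which may be technical. An array gave between 18272 and 20734 values, and 18525 features could be tested. Of these, 14632 were named to 1 of 13379 genes. The number of arrays limits the precision of each value. Differences are given on the log2 scale with their standard error, positive where the region named first was higher. This direction is likely, not stated, because the labels do not say which dye was the numerator of the ratio.

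The ends of the axis were compared to find genes graded from rostral to caudal neocortex. Nr2f1, a nuclear receptor gene long known for its gradient across the cortical sheet, was 2.03-fold lower in rostral than in caudal pools (log2 difference -1.02 ± 0.07, n = 3 pools per region, limma adjusted p = 0.0138). Scrn1, which encodes secernin 1, was 2.94-fold higher in rostral pools (1.56 ± 0.11, limma adjusted p = 0.0138), the largest difference among the genes that passed. Etv1, an ETS transcription factor gene and a known target of FGF signalling, was 1.74-fold higher in rostral pools (0.80 ± 0.07, limma adjusted p = 0.0272). Vim, the intermediate filament gene of radial glia, was 1.42-fold lower in rostral pools (-0.51 ± 0.05, limma adjusted p = 0.0389).

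In all, 12 of the 18525 features passed in limma's test of rostral against caudal, each from a different gene, 9 higher in rostral and 3 higher in caudal pools, and 1464 had an unadjusted p under 0.05. The other rostral genes were Dct, an enzyme of melanin synthesis (1.15 ± 0.11), Pdzph1 (0.96 ± 0.08), the arsenite methyltransferase gene As3mt (0.93 ± 0.08), the urea transporter gene Slc14a2 (0.87 ± 0.09), the noncoding RNA Pantr2 (0.73 ± 0.07), 4933424G05Rik (0.51 ± 0.05) and the growth factor gene Ptn (0.49 ± 0.05). The remaining caudal gene was Laptm4b, a lysosomal membrane protein (-0.47 ± 0.05). Limma's adjusted p for these 8 genes lay between 0.0272 and 0.0492. In each of the 12, the 3 rostral and the 3 caudal pools did not overlap, which chance gives in 10% of features and choice by a large difference makes likely. The middle mean lay between those of the ends in all 12, which the same choice favours. Scrn1 stepped from 0.80 ± 0.18 (SD) in rostral to -0.05 ± 0.14 in middle and -0.75 ± 0.09 in caudal pools, relative to the mean of the 9 pools. Nr2f1 went from -0.55 ± 0.12 to 0.08 ± 0.04 and 0.47 ± 0.04, whereas Slc14a2 was at 0.57 ± 0.06 in rostral, -0.28 ± 0.05 in middle and -0.30 ± 0.17 in caudal pools. Another probe of Nr2f1 gave the same difference between the ends (-1.02 ± 0.17, limma unadjusted p = 0.00047), but placed the larger step on the caudal side (-0.37 ± 0.17 for rostral against middle and -0.65 ± 0.17 for middle against caudal). The count did not withstand the loss of any pool: it was 4 without middle replicate 1 and 0 with each of the other 8 pools left out in turn. A pool left out takes its 4 arrays with it and lowers the residual degrees of freedom, so lost power alone could lower the count. With 1 array left out the count was between 2 (array 13) and 14 (array 15). It was 3 without array 9, 5 without array 6, 6 without array 7 or 14 and 7 without array 3, 5, 11 or 16. It was 0 without centring of the arrays, with the profile of the Gapdh control spots as a covariate, or with either division into sets of pools that share arrays as a block, and 2 without the 4 arrays that held most capped ratios. It was 46 among features measured on all 18 arrays and 47 without the noisiest 25% of features, and both of these sets held all 12.

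**Figure D1:**
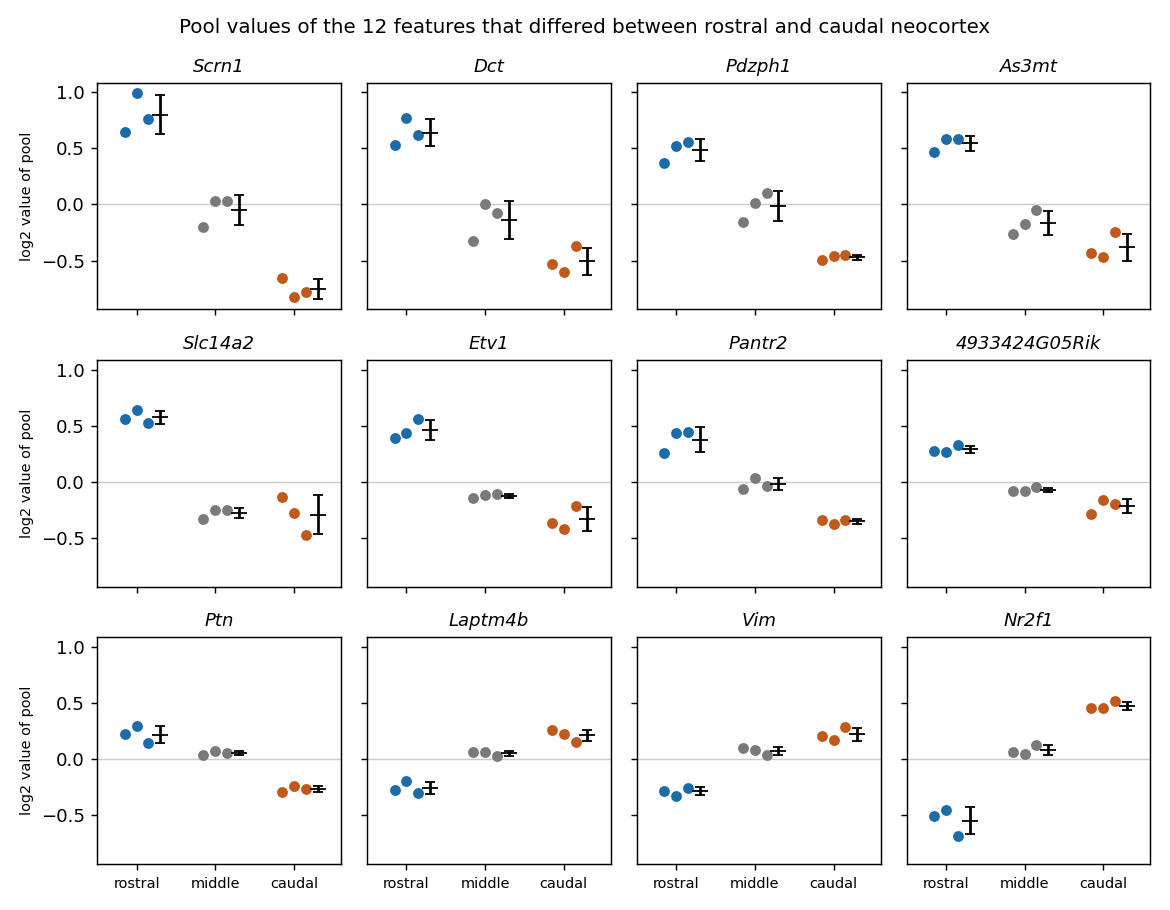
Log2 value of each pool, relative to the mean of the 9 pools, for the 12 genes that differed between rostral and caudal neocortex. Dots are pools, 3 per region, and the bar beside them is the mean ± SD; Scrn1 fell from a rostral mean of 0.80 to a caudal mean of -0.75, and Nr2f1 rose from -0.55 to 0.47.

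Of the genes next in rank for rostral against caudal, none passed. Higher rostral values were seen for Amer1 (0.50 ± 0.06), Sfrp1, a secreted WNT antagonist (0.73 ± 0.09, and 0.94 ± 0.13 with another probe), and Pou3f2, a POU transcription factor (0.68 ± 0.08), each at a limma adjusted p of 0.0571. A further probe of Pou3f2 gave -0.00 ± 0.05. Ltbp1 (-1.08 ± 0.12) and Zcchc12 (-0.71 ± 0.09) had higher caudal values at the same adjusted p. Tenm2, a teneurin of neuronal surfaces, had -0.77 ± 0.10 (limma adjusted p = 0.0619), and its other probes gave -0.59 ± 0.13 and -0.35 ± 0.10. Rbm20 (-0.63 ± 0.08, and -0.11 ± 0.25 with another probe), Cthrc1 (-0.38 ± 0.05), Slc25a3 (-0.38 ± 0.05), Hpca (-0.53 ± 0.07), Vcam1 (-0.50 ± 0.07) and Cryab (-0.76 ± 0.11) followed, with limma adjusted p between 0.0619 and 0.0806.

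Genes reported in textbooks as rostral were tested as a list. It shares 9 of its 11 members with the FGF pathway list, which is thus no separate evidence. Of the 11, 9 were measured. As a set they were higher in rostral than in caudal pools (camera, Up, adjusted p = 0.0248), a call lost with an estimated correlation (adjusted p = 0.515 with an estimated correlation; 0.000961 to 0.515 over 17 alternatives). Of the 9, Etv1 passed over all features, and 3 passed adjusted over the list alone: Etv1, Spry2 (0.46 ± 0.06), a feedback inhibitor of FGF signalling, and Etv5 (0.31 ± 0.09, with another probe at -0.06 ± 0.08). Pax6 had 0.31 ± 0.20 (and 0.32 ± 0.07 with another probe, limma unadjusted p = 0.00172), Etv4 0.03 ± 0.06 and Fgf17 0.02 ± 0.06. Fgf8 had -0.08 ± 0.06, Spry4 -0.17 ± 0.51 and Dusp6 -0.62 ± 0.44, and none of these 6 passed with the probe that stood for it. The set fell short of the threshold without rostral replicate 2 (adjusted p = 0.0677), rostral replicate 3 (0.147), middle replicate 2 (0.0559) or caudal replicate 2 (0.110), and with the Gapdh covariate (0.0675). Of the list of reported caudal genes, 9 of 13 were measured and the set missed the threshold (camera, Down, adjusted p = 0.0524, 0.442 with an estimated correlation and 0.00478 with fry). Nr2f1 alone passed, over all features and adjusted over the list alone. Emx2 had -0.25 ± 0.08, Wnt5a -0.09 ± 0.07, Lef1 -0.05 ± 0.05, Axin2 -0.02 ± 0.06, Wnt3a -0.01 ± 0.08, Wnt2b -0.33 ± 0.75, Fgfr3 0.03 ± 0.07 and Wnt8b 0.08 ± 0.07. These 2 lists were also used to settle the direction of the ratio, so they are no independent evidence of which end was higher.

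Meningeal and mesenchymal markers were lower in rostral than in caudal pools as a set (19 of 21 measured, 18 below 0 and 1 above, median -0.16; camera, adjusted p = 6.1e-06, and 0.442 with an estimated correlation). Its adjusted p over 17 alternatives ran from 1.27e-07 to 0.442. None of the 19 passed over all features, and 4 fell adjusted over the list alone: Ptgds, a prostaglandin synthase of the leptomeninges (-0.66 ± 0.13), the proteoglycan gene Dcn (-0.39 ± 0.09), the chemokine gene Cxcl12 (-0.27 ± 0.07) and Fn1 (-0.17 ± 0.05, and -0.08 ± 0.08 with another probe). The set stayed past the threshold whichever pool was left out, with an adjusted p of at most 0.00169. The rostral pools were uneven: the median of the set was 0.04 in rostral replicate 1, above each middle pool, and -0.09 and -0.13 in the other 2, against 0.06, 0.06 and 0.12 in the caudal pools. Ribosomal protein genes were also lower in rostral than in caudal pools (62 measured, 55 below 0 and 7 above, median -0.09; camera, adjusted p = 1.68e-06, and 0.662 with an estimated correlation), and 3 of them fell adjusted over the list alone, Rpl13 (-0.40 ± 0.08), Rps4l (-0.39 ± 0.08) and Rps10 (-0.37 ± 0.08). The correlation estimated between the ribosomal genes was 0.766, far above the preset 0.01, so the p-values of this set at the preset are too small. The adjusted p of the set ran from 1.12e-17 to 0.663 over 17 alternatives. The pools of the ends overlapped: the set medians were -0.00, -0.01 and -0.21 in rostral replicates 1 to 3 and -0.13, 0.07 and 0.12 in caudal replicates 1 to 3, and caudal replicate 1 was low in its Gapdh control spots too (-0.14). That call was lost without rostral replicate 3 (adjusted p = 0.258) and with fry (0.383), and the set turned to the other side with the Gapdh control spots as a covariate (adjusted p = 0.663).

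Proliferation genes missed the threshold as a set between the ends (25 of 28 measured, camera adjusted p = 0.0592, and 0.515 with an estimated correlation). None passed over all features. Adjusted over the list alone Rrm2 (0.56 ± 0.07), Mcm3 (0.45 ± 0.06) and Hmgb2 (0.31 ± 0.06) rose and Ccnd2 fell by 0.22, although its other probe gave 0.25 ± 0.09. FGF pathway genes went both ways (18 of 20 measured, adjusted p = 0.49), and Etv1 passed over all features. Etv1, Spry2 and Etv5, also in the reported rostral list, rose adjusted over the list alone, and Flrt3 (-0.47 ± 0.10) and Fgfr2 (-0.18 ± 0.05) fell. Radial glia genes, all 18 measured, did not pass as a set (adjusted p = 0.656; its median was 0.00, its mean -0.01 and its test pointed down). Vim passed over all features, and adjusted over the list alone Vim and the cortical selector gene Lhx2 (-0.31 ± 0.07) fell and the glutamate transporter gene Slc1a3 (0.32 ± 0.05, and 0.32 ± 0.29 and 0.22 ± 0.06 with other probes) rose. The list of Eph receptors, ephrins, cadherins and other regional genes had an adjusted p of 0.263 (19 of 22 measured), with Crym (-0.44 ± 0.07) and Lmo4 (-0.41 ± 0.08), which belong to none of the named families, falling adjusted over the list alone. WNT and BMP genes of the dorsal midline had the same adjusted p (25 of 28 measured), with Wls (-0.41 ± 0.09) the only member to pass adjusted over the list alone. Intermediate progenitor genes, all 13 measured, had an adjusted p of 0.606, with 0 members passing adjusted over the list alone in limma and Insm1 (0.29 ± 0.07) and Gadd45g (-0.24 ± 0.07) nearest.

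Rostral against middle neocortex asked where along the axis such genes change. No feature passed (0 in limma, with 973 at an unadjusted p under 0.05 and a lowest adjusted p of 0.28). The lowest p-values belonged to Slc14a2 (0.85 ± 0.09), As3mt (0.71 ± 0.08), Etv1 (0.59 ± 0.07) and Nr2f1 (-0.63 ± 0.07, and -0.37 ± 0.17 with another probe), each at a limma adjusted p of 0.28, then Scrn1 (0.85 ± 0.11) and the cyclin gene Ccnd2 (-0.38 ± 0.05, and 0.28 ± 0.09 with another probe) at 0.287. Dct (0.78 ± 0.11), 4933424G05Rik (0.36 ± 0.05) and Vim (-0.36 ± 0.05) followed at 0.384. The other positive values were Fnbp1 (0.40 ± 0.06, its other probes between -0.07 and 0.11), Rwdd3 (0.52 ± 0.08), Gnaq (0.76 ± 0.12, its other probes 0.18 and 0.12), Wnt8b (0.43 ± 0.07), Pdzph1 (0.50 ± 0.08) and Pantr2 (0.40 ± 0.07). The other negative values were Ncbp3 (-0.38 ± 0.06), Laptm4b (-0.31 ± 0.05), the retinoic acid binding protein gene Crabp1 (-0.63 ± 0.10), 1110008P14Rik (-0.46 ± 0.08), Trpv6 (-0.37 ± 0.06), 9130401M01Rik (-0.32 ± 0.06), Slc25a3 (-0.27 ± 0.05), Rpl13 (-0.43 ± 0.08) and Rpl29 (-0.30 ± 0.06). Limma's adjusted p for all these genes was between 0.28 and 0.587.

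Ribosomal protein genes were lower in rostral than in middle pools, with 60 of 62 below 0 and a median of -0.15 (camera, adjusted p = 1.48e-17, and 0.723 with an estimated correlation). The correlation estimated between the genes of this set was 0.766, far above the preset 0.01, so its p-values at the preset are too small. The adjusted p of the set ran from 5.81e-22 to 0.740 over 17 alternatives. None passed over all features, and Rpl13, Rpl29 and Rps10 (-0.37 ± 0.08) fell adjusted over the list alone. At the preset correlation the call was kept whichever pool was left out. The rostral values were uneven, however: the median of the set was -0.21 in rostral replicate 3 and -0.00 and -0.01 in the other 2, against a middle mean of 0.07. The call was lost with fry (adjusted p = 0.335), and the set turned to the other side with the Gapdh control spots as a covariate (adjusted p = 0.740). In those spots all rostral pools lay below all middle pools, so the covariate takes up much of this contrast whatever its cause. Over the 9 pools the median of the ribosomal genes followed that of the Gapdh control spots (Pearson r = 0.919, exact permutation p = 7.72e-05; Spearman rho = 0.95, exact permutation p = 0.000353; adjusted over 2 such relations 7.72e-05 and 0.000705). Without the 2 pools farthest from the median of the Gapdh spots r was 0.904 (exact permutation p = 0.00317). The other relation, of the median of 22 other abundant genes with the Gapdh spots, had r = 0.968 (exact permutation p = 1.65e-05, adjusted 3.31e-05) and rho = 0.933 (exact permutation p = 0.00075), and r = 0.941 without the same pools. These permutations take the pools as freely exchangeable, which they are not, since pools share arrays and belong to regions.

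No other list passed for rostral against middle. The nearest was the red blood cell list, with an adjusted p of 0.0633 (9 of 16 measured, camera, Down). The reported rostral list had 0.19 and the reported caudal list 0.195. Adjusted over their lists alone, Etv1 and Spry2 (0.31 ± 0.06) rose and Nr2f1 fell, and Wnt8b, in the caudal and dorsal midline lists, rose. In the radial glia list (adjusted p = 0.872, median 0.00, mean 0.01, test pointing down), Vim and Lhx2 (-0.30 ± 0.07) fell and Slc1a3 (0.28 ± 0.05, and 0.11 ± 0.29 and 0.23 ± 0.06 with other probes) and the fatty acid binding protein gene Fabp7 (0.32 ± 0.07) rose adjusted over the list alone, with 0 of the 18 passing over all features. Ccnd2 was the only proliferation gene to pass adjusted over the list alone (set adjusted p = 0.19). For the remaining lists the adjusted p was 0.783 for the FGF pathway, 0.9 for the dorsal midline, 0.8 for Eph receptors and cadherins, and 0.19 each for intermediate progenitors and meninges.

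Middle against caudal neocortex asked the same of the caudal part of the axis. Again 0 features passed in limma, with 901 at an unadjusted p under 0.05 and a lowest adjusted p of 0.394. The largest values with the lowest p in the middle pools were Cdk5rap3 (0.88 ± 0.15), Mea1 (0.80 ± 0.11), Scrn1 (0.71 ± 0.11), Pqbp1 (0.52 ± 0.08), Acss1 (0.50 ± 0.07), Pgpep1 (0.45 ± 0.07), Gucy1b2 (0.45 ± 0.07), the replication licensing gene Mcm3 (0.41 ± 0.06), Atpsckmt (0.40 ± 0.06), the chromatin protein gene Hmgb2 (0.38 ± 0.06), the cell cycle inhibitor gene Cdkn2d (0.34 ± 0.05) and Spsb2 (0.31 ± 0.05). Those for the caudal pools were Ppm1h (-1.04 ± 0.20), Zfp810 (-0.92 ± 0.18), Ltbp1 (-0.85 ± 0.12), Ptgds (-0.82 ± 0.13), Mrgprf (-0.69 ± 0.14), Zcchc12 (-0.61 ± 0.09), the neuronal membrane glycoprotein gene Gpm6a (-0.45 ± 0.09, and -0.46 ± 0.09 with another probe), Loxl1 (-0.42 ± 0.09), Slf1 (-0.40 ± 0.06), Cfb (-0.40 ± 0.08), Nr2f1 (-0.39 ± 0.07, and -0.65 ± 0.17 with another probe) and Wnt8b (-0.35 ± 0.07). Limma's adjusted p for these genes was 0.394 or 0.413.

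Proliferation genes were higher in middle than in caudal pools as a set, 24 of 25 above 0 with a median of 0.10 (camera, adjusted p = 2.57e-07, and 0.112 with an estimated correlation). Its adjusted p over 17 alternatives ran from 1.1e-08 to 0.112. None passed over all features, and Mcm3, Hmgb2 and the ribonucleotide reductase gene Rrm2 (0.36 ± 0.07) rose adjusted over the list alone. The set call was kept whichever pool was left out, with an adjusted p of at most 0.000168. Without centring of the arrays its adjusted p (camera) was 0.0330. The signs of single members are relative to the array medians, as without centring the median over all features was -0.17 for middle against caudal. Meningeal markers were lower in the middle than in the caudal pools (15 of 19 below 0, median -0.09, adjusted p = 0.00261, and 0.378 with an estimated correlation), Ptgds being the 1 member that fell adjusted over the list alone. Its adjusted p over 17 alternatives ran from 0.00035 to 0.378. This call was lost without caudal replicate 3 (adjusted p = 0.0990) and with fry (0.240).

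Ribosomal protein genes were higher in the middle than in the caudal pools (53 of 62 above 0, median 0.06, adjusted p = 0.00706, and 0.876 with an estimated correlation), with 0 members passing in limma adjusted over the list alone. With an estimated correlation of 0.766 between these genes, the p of the set at the preset 0.01 is too small here too. The adjusted p of the set ran from 1.53e-07 to 0.876 over 17 alternatives. They turned to the other side without centring of the arrays (adjusted p = 0.171), with the Gapdh spots as a covariate (0.588) and without caudal replicate 1 (0.329), and the call was lost without middle replicate 2 (0.0882) and with fry (0.771). The list of Eph receptors, ephrins, cadherins and other regional genes was lower in the middle pools at an adjusted p of 0.0456, and 0.44 with an estimated correlation (11 of 19 below 0, median -0.05, range over 17 alternatives 0.00771 to 0.44). Crym (-0.29 ± 0.07) and Lmo4 (-0.30 ± 0.08), which belong to none of the named families, came nearest, at 0.0867 adjusted over the list alone. That set call was lost without rostral replicates 1 (0.153), 2 (0.169) or 3 (0.0610), middle replicate 2 (0.330) and caudal replicates 1 (0.164) or 3 (0.302). It was lost as well without centring (0.119), with fry (0.310), with the mean of all features of a gene (0.0717), with the Gapdh covariate (0.129) and without the 4 arrays with most capped ratios (0.121). The reported rostral list was higher in the middle pools at an adjusted p of 0.0477, and 0.447 with an estimated correlation (7 of 9 above 0, median 0.10, range over 17 alternatives 0.000864 to 0.447), with 0 members passing in limma adjusted over the list alone. It was lost without rostral replicate 2 (0.108), middle replicates 2 (0.106) or 3 (0.158) and caudal replicates 1 (0.0955) or 2 (0.427), and also without centring (0.197), with fry (0.327) and with the Gapdh covariate (0.145).

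Intermediate progenitor genes missed the threshold for middle against caudal (camera adjusted p = 0.0513, and 0.378 with an estimated correlation) and passed with fry (0.03). Of the 13, Insm1, a zinc finger factor of newly committed progenitors (0.39 ± 0.07), Mfng (0.18 ± 0.05) and Rgs16 (0.16 ± 0.05) rose adjusted over the list alone. For the reported caudal list the adjusted p was 0.0764, and 0.03 with fry, with Nr2f1 and Wnt8b falling adjusted over the list alone. Fabp7 (-0.34 ± 0.07) fell adjusted over the radial glia list alone, whose set had an adjusted p of 0.822. The dorsal midline list had an adjusted p of 0.152 and the FGF pathway 0.0739.

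**Figure D2:**
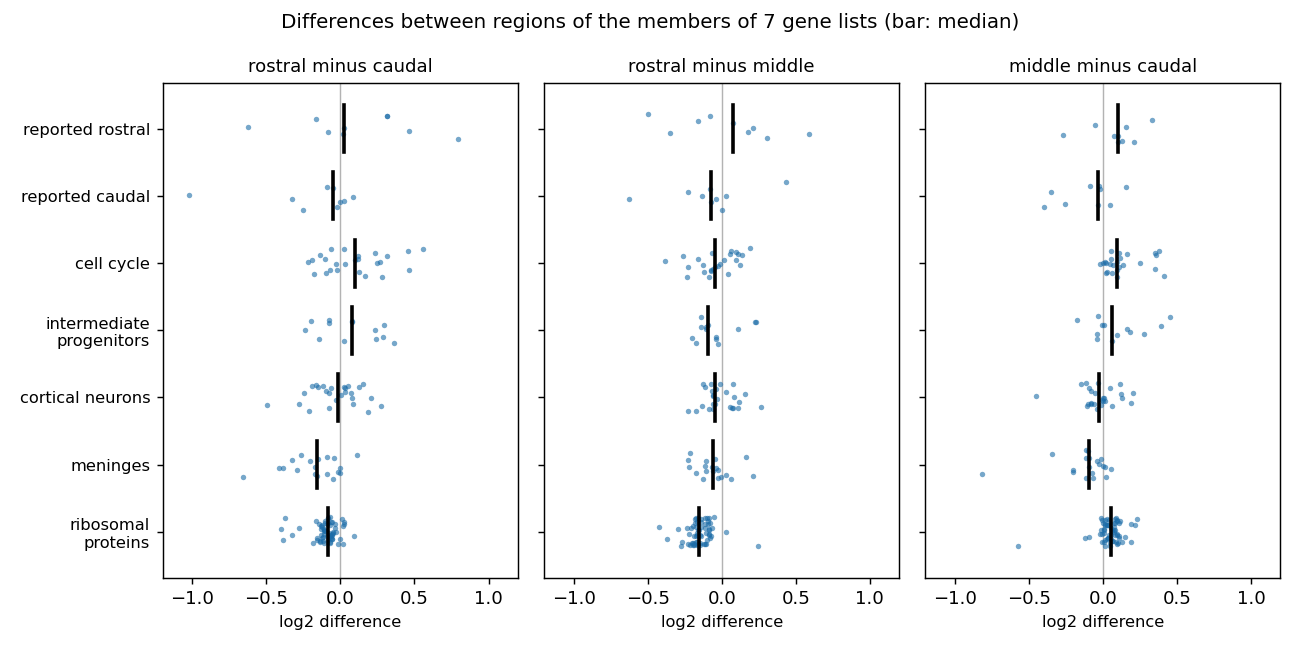
Log2 differences of the measured members of 7 gene lists, for rostral minus caudal, rostral minus middle and middle minus caudal; each dot is a gene and the black bar is the median of its list. All differences are relative to the array medians. Proliferation genes lie above 0 for middle minus caudal in 24 of 25 cases and meningeal genes below 0 for rostral minus caudal in 18 of 19. Ribosomal genes lie below 0 for rostral minus middle in 60 of 62 cases, and their direction for middle minus caudal (median 0.06) turns without centring of the arrays.

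The 3 regions were also compared in a single test, and the middle was set against the mean of the ends. Nr2f1 and Scrn1 were the 2 features that passed limma's F test (adjusted p = 0.047 for both, 1243 features at an unadjusted p under 0.05), and 0 remained with each of the 9 pools left out in turn. Pdzph1, Etv1, As3mt, Pantr2 and Slc14a2 followed at a limma adjusted p of 0.0767, Dct at 0.0928, and 4933424G05Rik and Vim at 0.0993. The count of the F test was also 0 without centring, with scaled arrays, with features on at least 10 arrays, with capped ratios kept and with the Gapdh covariate. It was 20 among features on all 18 arrays and 15 without the noisiest 25% of features. No feature passed for the middle against the mean of the ends (0 in limma, 752 at an unadjusted p under 0.05, lowest adjusted p 1.0). The lowest p-values there belonged to Wnt8b, a WNT ligand of the cortical hem, with a middle value below the ends (-0.39 ± 0.06), Ccnd2 (0.27 ± 0.04, and -0.16 with another probe), Pgpep1 (0.39 ± 0.06), Mrgprf (-0.68 ± 0.12), Crabp1 (0.52 ± 0.09), Gnaq (-0.57 ± 0.10, and -0.31 and -0.09 with other probes), Akr1a1 (0.23 ± 0.04), Fabp7 (-0.33 ± 0.06), Ppm1h (-0.94 ± 0.17) and Loxl1 (-0.40 ± 0.07).

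Markers of other tissues that a dissection could carry along were tested as lists as well. Red blood cell genes had an adjusted p of 0.0716 for rostral against caudal (9 of 16 measured), with the haem synthesis gene Alas2 (-0.32 ± 0.07) falling adjusted over the list alone. For middle against caudal it was 0.879, with a median of -0.01 and a mean of 0.02. Ventral telencephalon genes (19 of 24 measured) had adjusted p of 0.615, 0.359 and 0.734 for rostral against caudal, rostral against middle and middle against caudal (sets tested with camera). In the first of these the median was 0.01 while the mean was -0.03 and the test pointed down, and adjusted over the list alone Foxp2 (0.41 ± 0.08) rose and Gsx2 (-0.53 ± 0.12) fell. In the same order, the adjusted p was 0.602, 0.57 and 0.832 for choroid plexus (8 of 12 measured), and 0.656, 0.911 and 0.734 for diencephalon (8 of 12). It was 0.606, 0.635 and 0.832 for endothelium (14 of 15), 0.224, 0.642 and 0.465 for microglia (12 of 14), and 0.517, 0.783 and 0.798 for surface epithelium (7 of 10). Immediate early and heat shock genes, signs of handling, had 0.606, 0.911 and 0.756 (14 of 15). None of the members of these 6 lists passed in limma, over all features or adjusted over the list alone, among them Cldn5 (-0.14 ± 0.07), Mrc1 (-0.30 ± 0.10) and Btg2 (0.23 ± 0.07) for rostral against caudal. Medians and means had opposite signs for endothelium in rostral against caudal (-0.06 and 0.03) and rostral against middle (-0.01 and 0.01), and, for rostral against middle, in diencephalon (-0.00 and 0.16), in handling genes (-0.00 and 0.00) and in the dorsal midline list (-0.00 and 0.02).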

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

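Capped ratios kept, the 4 arrays with over 100 capped ratios left out, the Gapdh covariate, the lowess correction and the blocks of pools that share arrays were chosen after the results were seen; the other settings were planned. For rostral against caudal (12 features), the count was 8 with scaled arrays, 10 with a robust prior, 10 with the lowess correction, 10 at a difference of at least 0.5, 12 without a dye term and 12 with capped ratios kept. It moved to 46 for features on all 18 arrays and 47 without the noisiest 25% of features, and to 7 for features on at least 10 arrays. The first 2 of these settings test fewer features, and the prior of limma is estimated anew in them. Without the noisiest 25%, 1531 features had an unadjusted p under 0.05, against 1464 in the main fit. The count was 0 without centring, 0 with the Gapdh covariate, 0 with either block of pools that share arrays, and 2 without the 4 arrays, and the cause was not tested. Among all 3 regions (2 features) the counts were 20 on all 18 arrays, 15 without the noisiest 25%, and 0 without centring, with scaled arrays, on at least 10 arrays, with capped ratios kept, with the Gapdh covariate, with either of these blocks and without the 4 arrays. With the 18 arrays taken as independent, limma called 1325 features for rostral against caudal, 707 for rostral against middle, 501 for middle against caudal, 1494 among all regions and 291 for the middle against the ends. With array noise alone as the error it called 1564, 994, 645, 1794 and 533. Both of these ignore the spread between pools of a region. The counts of 0 for rostral against middle, middle against caudal and the middle against the ends stayed at 0 in all other settings run, leave-outs included.

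With the replicate number as a block, rostral against caudal gave 0 features, all regions 0 and the other comparisons 0, and gene lists 3, 2 and 4 for rostral against caudal, rostral against middle and middle against caudal. In the block the reported rostral list for middle against caudal had an adjusted p of 0.0526. Whole profiles gave no sign of pairing by number, and the labels do not tie numbers to embryos. Over 9 pairs the correlations of same-numbered pools lay between -0.43 and -0.06, where array noise alone gives -0.2. Of the 9 pairs 0 were over 0.1, and pools correlated best with their own number in 0 of 18 cases. Same-numbered pools never share an array while other pairs do, so the layout favours both counts of 0. They cannot exclude pairing.

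Leaving out each pool gave between 0 and 4 features for rostral against caudal (4 without middle replicate 1, 0 without each of the other 8 pools) and 0 among all regions. Leaving out each array gave between 2 and 14, and between 0 and 2 among all regions (2 without array 7 or 15, 1 without array 9, 10 or 18, 0 without each of the others). The count for rostral against caudal was 2 without array 13, 3 without array 9, 5 without array 6, 6 without array 7 or 14, and 7 without array 3, 5, 11 or 16.

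Gene lists past the threshold for rostral against caudal (3), rostral against middle (1) and middle against caudal (5) became 0, 0 and 0 with an estimated correlation, 3, 0 and 3 with fry, 5, 2 and 3 without centring, 2, 0 and 2 with the Gapdh covariate, and 4, 2 and 4 without the 4 arrays. Leaving out each pool gave 1 to 4, 1 to 3 and 2 to 6 lists. The ribosomal set changed direction with the Gapdh covariate in the 3 comparisons (adjusted p = 0.663, 0.740 and 0.588), and for middle against caudal also without centring (0.171) and without caudal replicate 1 (0.329). Its adjusted p in that comparison was lowest without caudal replicate 3 (1.53e-07). Over 17 alternatives the adjusted p of the meningeal set for rostral against caudal ranged from 1.27e-07 to 0.442 and that of the proliferation set for middle against caudal from 1.1e-08 to 0.112, and each was past the threshold in 16. Genes named for their size or lowest p were run in 15 alternatives and did not reverse, while list members named only as such were not run. Sizes ranged from 1.45 to 1.64 for Scrn1, 0.97 to 1.10 for Nr2f1 and, the widest of the 12, 0.33 to 0.54 for Laptm4b (absolute log2 differences). Of the results of the 12 in these settings 30 stayed past the threshold and 150 did not; the 30 were 12 with the arrays taken as independent, 12 without a dye term, 4 without middle replicate 1 and 2 without the 4 arrays. The table gives ratios without intensities, so signal over background could not be used to judge dim features.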

Other observations

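The tests of the Gapdh spots, of the meningeal markers and of Xist by pool number were chosen after the results they bear on were seen. The counts over other splits were set before. The list of other abundant transcripts was written before its test, but is not among the lists fixed before the data were examined.

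Neuronal genes went both ways along the axis. Of the cortical neuron list 26 of 27 were measured, and its set had an adjusted p (camera) of 0.49 for rostral against caudal, 0.635 for rostral against middle and 0.798 for middle against caudal. For rostral against caudal 0 members passed over all features in limma and 4 adjusted over the list alone: the layer 5 regulator Bcl11b (0.21 ± 0.05, and 0.46 ± 0.08 with another probe) and the synaptotagmin gene Syt1 (0.28 ± 0.06) rose, and Fezf2 (-0.28 ± 0.05), also a deep-layer regulator, and the filament gene Ina (-0.25 ± 0.05) fell. Syt1 (0.26 ± 0.06) and Fezf2 (-0.23 ± 0.05) passed in the same way for rostral against middle. Bcl11b and Fezf2, both known from subcerebral projection neurons, thus had opposite signs, a difference between genes that was not itself tested.

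Of the Cajal-Retzius genes 8 of 10 were measured, and the sets had adjusted p of 0.428, 0.635 and 0.734 in the same order of comparisons. Reln, the secreted signal of these cells, was -0.36 ± 0.08 for rostral against caudal and -0.31 ± 0.08 for middle against caudal and fell in both adjusted over the list alone (0.0226 and 0.0495), with limma adjusted p of 0.227 and 0.585 over all features. Another probe of Reln gave -0.04 ± 0.10 and -0.05 ± 0.10. Of the retinoid genes 12 of 16 were measured (set adjusted p = 0.49, 0.799 and 0.822). Crabp1 fell for rostral against middle adjusted over the list alone (-0.63 ± 0.10, 0.00548), and had -0.23 ± 0.10 for rostral against caudal and 0.40 ± 0.10 for middle against caudal.

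The ribosomal protein genes, lower in rostral than in middle pools by a median of -0.15 (95% bootstrap interval over genes, not pools, -0.17 to -0.14, as for the medians below), may reflect a shift of abundant transcripts between arrays and not a regional difference in these genes. Of 30 other abundant housekeeping genes, 22 were measured, 21 of them were below 0, and their median was -0.14 (-0.17 to -0.06), but for rostral against caudal it was -0.03 (-0.08 to 0.00, 15 of 22 below 0, camera p = 0.0141, and 0.334 with an estimated correlation) against -0.09 (-0.11 to -0.07) for the ribosomal genes, and for middle against caudal 0.06 for both. The ribosomal profile followed that of the Gapdh control spots over the 9 pools (r = 0.919), and with the Gapdh profile as a covariate its median was 0.03 for rostral against middle and 0.02 for rostral against caudal. The Gapdh spots themselves stood at -0.09 ± 0.06 (SD) in rostral, 0.08 ± 0.01 in middle and 0.01 ± 0.14 in caudal pools. Rostral and middle pools did not overlap in them, so the covariate takes up much of that contrast whatever its cause. For rostral against middle the other abundant genes moved with the ribosomal genes, as a shift tied to abundance or signal would give. RNA amounts, labelling, the authors' processing and a regional difference shared by these genes are not told apart by these tests. For the ends the abundant genes moved the same way by a smaller median, and a regional difference in ribosomal protein transcripts stays open, since it was not tested apart from that shift. Ratios of transcripts do not measure ribosomes.

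The meningeal set, lower in rostral than in caudal pools by a median of -0.16 (95% bootstrap interval over genes, not pools, -0.27 to -0.05), could come from more meningeal tissue in the caudal pools. The 4 fibrillar collagen genes of the list, typical of meningeal fibroblasts, had a mean difference of -0.065 (95% interval over pools -0.20 to 0.07), which includes both 0 and the median of the list. With the Gapdh covariate the median was -0.11 (-0.25 to -0.02) and the set stayed past the threshold at the preset correlation (camera, adjusted p = 0.00847) but not at an estimated one (0.782), so whether the shift of abundant transcripts had a part in it stays open; the change of the median was not tested. Of the 21 genes, 1 is also in the retinoid list (Aldh1a2), Cxcl12, Fn1 and Sparc are known outside meninges too, and ratios give no levels to say which the neocortex itself expressed. Regional expression of these genes, in neural or in meningeal cells, cannot be told apart from carried-over tissue here, because the pools hold whole tissue and the collagen interval is wide.

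Xist, the RNA of the inactive X chromosome, differed by pool number in each region: its mean over the 3 pools of a number was -0.36 ± 0.29 (SD) for number 1, 0.05 ± 0.01 for number 2 and 0.31 ± 0.04 for number 3. The Y-linked gene Kdm5d had 0.10 ± 0.01, -0.03 ± 0.03 and -0.07 ± 0.05, and over the 9 pools the 2 genes were opposed (Pearson r = -0.796, exact permutation p = 0.00599; Spearman rho = -0.817, exact permutation p = 0.0108; without the 2 pools farthest in Xist r = -0.930, exact permutation p = 0.00952). The permutations over pools take them as freely exchangeable, which pools that share arrays are not. A candidate explanation is that pools of a number share embryos and thus sex makeup. Of the 36 ways to assign numbers within regions 1, the real one, gave so large a spread of Xist (exact p = 0.0278, the smallest these can give, and 0.111 adjusted over 4 genes), against 2 for Kdm5d (exact p = 0.0556), 25 for Eif2s3y (0.694) and 29 for Uty (0.806). Eif2s3y and Uty gave no such spread. Uty was noisy, with a residual SD between arrays of 0.938, against 0.240 for Xist, 0.129 for Kdm5d and 0.171 for Eif2s3y, so it bears little on the question. The labels do not link the numbers to embryos, so the matter stays open. The set of Xist and Y-linked genes (4 of 5 measured) had adjusted p of 0.737, 0.57 and 0.734 between regions (camera), which bears on neither view.

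Other splits of the pools were counted for each result. For any difference among the 3 regions, 3 of 100 splits of the 9 pools, the real one included, gave as many features as the 2 found. This share does not exclude chance, because the pools are not freely exchangeable: pools of a region never share an array, while other splits can group pools that do. Another split gave 244. That split grouped rostral 1 with middle 3 and caudal 2, rostral 2 with middle 1 and caudal 3, and rostral 3 with middle 2 and caudal 1. It follows a structure in the layout of the arrays: each of its groups is a set of 3 pools that share 3 arrays. The only other division into such sets gave 1 feature. The 244 features had a median residual SD between arrays of 0.746, against 0.256 over all features and 0.207 in the 12 that differed between rostral and caudal, 55.3% of them were among the noisiest 25%, and 0 were among the 12. The split gave 147 features without the noisiest 25%. It gave 17 among the 12571 features on all 18 arrays, where rostral against caudal gave 46, so its count depended on features with missing arrays. Array noise is not excluded for the remaining features, which carry it too. With these sets as a block, rostral against caudal gave 0 features (limma, 1890 at an unadjusted p under 0.05) and the test of all 3 regions 0 (1588). Each set holds 1 pool of each region, so the block leaves the regional differences as they are and takes 2 of the 6 residual degrees of freedom. More features had an unadjusted p under 0.05 with it than the 1464 and 1243 without it. The loss of the adjusted calls therefore does not tie the 2 features to this structure.

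For the pairs of regions the 6 pools make 10 splits, too few for a share under 0.05. Rostral against caudal gave 12 features, as many in 1 of the 10 splits, and 0 in the highest other. Rostral against middle gave 0 (10 of 10 as many, highest other 3) and middle against caudal 0 (10 of 10, highest other 0). Gene lists numbered 3 for rostral against caudal (1 of 10, highest other 2), 1 for rostral against middle (7 of 10, highest other 3) and 5 for middle against caudal (1 of 10, highest other 3). For the middle against the ends the count was 0, which any split reaches (100 of 100), so the comparison decides nothing. The highest other, 260, came from the same split as the 244.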
